A study of Mus musculus with 8 samples.

How the data were processed

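Affymetrix MOE430 2.0 arrays, which carry probe sets for mouse transcripts, were used by the authors to measure gene expression in 4 Plagl2 knockout and 4 wild-type small intestines at 18.5 days post coitum. Per the labels, total RNA was isolated with a column kit, copied from an oligo-dT primer with a T7 promoter and transcribed into biotinylated cRNA. The deposited table gives 1 signal intensity per probe set and sample, on a linear scale, for 45101 probe sets. The mean of each array, after trimming 2% of the values at each end, was about 150.05 in the table, so the authors' scaling of each array to a common mean is already in the values. The signal algorithm and its software are not given in the sources used here, and the table holds no detection calls. It holds 1080 values of 0. No value column was left without a sample.

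The 64 Affymetrix control probe sets were left out of the tests. Of all 45101 probe sets, 34958 are listed with 1 gene symbol in the platform annotation, 932 with several and 9211 with none. Symbols were checked by Entrez ID against the RefSeq gene table of assembly GRCm38.p6, in which 34754 of those with 1 symbol were found and 0 symbols had to be updated. That table also gave the order of genes around Plagl2.

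Signals were transformed as log2(signal + 16). The array medians on this scale differed by 0.158 at most, under the limit of 0.32 set for keeping the authors' scaling, so no further normalization was applied. Of the 45037 probe sets other than controls, the 40% with the lowest mean were left out (mean signal under about 23.0), which left 27022 for the test. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with genotype as the only term, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A gene was represented by its tested probe set with the highest mean, which gave 12838 genes. Fold changes are knockout over wild-type on the log2(signal + 16) scale, so the added 16 makes them smaller than ratios of raw signal where a group is dim. Errors of fold changes are standard errors from the same fit, and errors of signals are SDs of 4 arrays. Single measures of the arrays were compared with an exact two-sided permutation test, whose smallest possible p for 4 against 4 is 0.0286.

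There were 35 gene lists (pathways, cell types, possible neighbouring tissues, reported targets and neighbours of Plagl2), of which 33 had the 4 tested members needed for a set test. The test was camera with a preset correlation of 0.01, adjusted over the 33 lists. It was repeated with an estimated correlation and with fry, which asks whether the genes of a set move on balance one way and compares them with no other genes. Counts of members are given over all probe sets tested and adjusted over the list alone. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Plagl2, then the 12 genes highest and the 12 lowest by log2 fold change among those past the threshold with no overlap between the groups, without predicted genes. From each list it takes up to 5 members past the threshold with the smallest p, or 3 members by smallest p where none passed, and all neighbours of Plagl2 past the threshold. Other genes were chosen after their values were seen, and are said to be.

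The test was run on simulated data of the same size. Of 200 simulated changes in 27022 probe sets, 17 of 77 at 1.5-fold (22.1%), 40 of 58 at 2-fold (69%) and 58 of 59 at 4-fold (98.3%) of those tested were called, along with 2 of 26828 unchanged probe sets. In the real data 3238 probe sets were called. The adjusted threshold is stricter where fewer probe sets change, so these shares need not hold there. A list shifted by -0.5 was called and 0 of 32 unshifted lists were, in data without correlation between genes.

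Alternatives were no filter, a filter of 60%, quantile normalization, offsets of 1 and 64, the replicate number as a block, array weights, no intensity trend, an unmoderated linear model, stricter thresholds, the Xist signal or the 3' to 5' ratio of each array as a covariate, the mean of all probe sets of a gene, and each array left out in turn. Added after the data were seen were a fit without wild-type replicate 3 and knockout replicate 4, the arrays furthest from their group, and a fit of the 6 arrays without Xist signal. For arrays, their number limits the precision.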

Results

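The data describe gene expression in the small intestine of mouse fetuses at 18.5 days post coitum, in 4 samples lacking Plagl2 and 4 wild-type samples, with 1 array each. Plagl2 encodes a zinc finger transcription factor of the PLAG family. Median signals were 36 to 42 per array, and the correlation of log2 signals was 0.950 to 0.974 within a genotype and 0.926 to 0.948 between genotypes. The principal component with the largest share of the variance (44.3%) separated the genotypes, with knockouts at 35.7 to 40.7. On it, wild-type replicate 3 lay at -21.9 while the other wild-type arrays lay between -44.7 and -43.3. Xist, transcribed from the inactive X chromosome, gave signals of 1828 and 1410 in knockout replicates 2 and 3 and of at most 47 in the other 6 arrays. The Y-linked gene Eif2s3y gave 7 and 3 in those knockouts and 562 to 770 elsewhere. By these signals knockout replicates 2 and 3 were female and the other 6 samples male, so sex was not balanced between the genotypes. The mean log2 ratio of 3' to 5' control probe sets was 0.048 ± 0.035 (SD, n = 4) in knockouts and -0.016 ± 0.029 (SD, n = 4) in wild-types (difference 0.064, exact permutation p = 0.0286). With wild-type replicates 1 to 4 or knockout replicate 1 left out, that difference was 0.048 to 0.071 (exact p = 0.0571 to 0.0857). Taken singly, the actin ratio differed by 0.046 (exact permutation p = 0.286) and the Gapdh ratio by 0.082 (exact permutation p = 0.0857). A difference in RNA quality is therefore not established. The extraction text of all 8 samples speaks of wild-type intestines, while titles, source names and the series design give 4 knockouts. The labels do not say whether the samples come from separate litters, so p-values measure the spread between these samples.

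Plagl2 signal was lost in every knockout sample. Probe set 1417517_at gave 784 ± 58.9 (SD, n = 4) in wild-type and 6.25 ± 3.4 (SD, n = 4) in knockout intestine, and 1417519_at gave 799 ± 96.3 and 5.5 ± 4.4. On the log2 scale Plagl2 was lower by these 2 probe sets at -5.18 ± 0.14 (SE, adjusted p = 2.42e-09) and -5.26 ± 0.17 (adjusted p = 9.02e-09), and by 1442235_at at -1.84 ± 0.23 (adjusted p = 0.000276). Each of the 4 Plagl2 probe sets had no overlap between genotypes (exact permutation p = 0.0286, the smallest possible for 4 against 4), 1417518_at being too dim for the test across genes (37.5 against 6.25). The labels do not say which part of the gene is missing. The related gene Plagl1 had a log2 fold change of -0.29 (adjusted p = 0.239), and was called as lower without knockout replicate 4 (0.0469).

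The comparison of knockout with wild-type asks what the loss of this factor changes in the late fetal intestine, in which the series title points to the metabolism of chylomicrons, the lipoproteins that carry absorbed fat. Mamdc4 (1440333_at), which encodes an endosomal protein of fetal enterocytes, was among the lowest genes, with a signal of 4944 ± 338 (SD, n = 4) in wild-type and 43.5 ± 6.35 (SD, n = 4) in knockout intestine (log2 fold change -6.39 ± 0.11 SE, adjusted p = 1.87e-11). Arg2 (1418847_at), the mitochondrial arginase, was among the highest, going from 14 ± 4.24 to 2123 ± 603 (6.12 ± 0.20, adjusted p = 1.13e-08). Among the 12 highest genes were the dehydrogenase genes Adh4 (5.67), Rdh9 (4.26) and Rdh7 (3.43). Others of the 12 were the fatty acid transporter and acyl-CoA synthetase Slc27a2 (4.25), apolipoprotein Apoa2 (4.24), the alkaline phosphatase Akp3 (4.47) and the membrane mucin Muc3 (signal 162 to 3357). Slc5a12 (signal 7 to 477), Ces1f (2.25 to 245), Sult2b1 (20.8 to 468) and Cyp4f14 (6.5 to 227) were also among them. Signals of Adh4 rose from 17.8 ± 7.89 to 1708 ± 413 and those of Apoa2 from 97.5 ± 36.1 to 2168 ± 849 (SD, n = 4). Among the 12 lowest, beside Mamdc4 and Plagl2, were the neonatal Fc receptor gene Fcgrt (-3.83), the lysosomal sialic acid exporter Slc17a5 (-3.89), the sialyltransferase St3gal1 (-4.91), melanotransferrin Meltf (-4.13), coagulation factor F10 (-4.03) and alpha-fetoprotein Afp (-3.47). The others were Pdzk1ip1 (-4.43), Tdrp (-4.17), Sdr16c5 (-3.99) and Stra6l (-3.51). Where a group is dim, as the wild-types are for Arg2, Adh4, Rdh9, Slc5a12, Ces1f, Sult2b1 and Cyp4f14 and the knockouts for Plagl2 and Sdr16c5, the size and rank of the change depend on the added 16. For Ces1f the log2 fold change was 2.16 with an offset of 64 and 6.30 with an offset of 1. All of these genes were past the threshold with no overlap between groups, and none had a probe set called the opposite way. Afp lost its call without wild-type replicate 1, 2 or 4 or knockout replicate 2 or 3 (adjusted p = 0.0612 to 0.0803). In knockout replicate 4 it gave 4818, against 108 to 976 in the other knockouts, and without that array the log2 fold change of Afp was -4.53. Its log2 fold change was -1.41 with the Xist signal as a covariate (adjusted p = 0.153) and -1.44 in the arrays without Xist signal (0.0921), and with the 3' to 5' ratio as a covariate its adjusted p was 0.236.

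**Figure D1:**
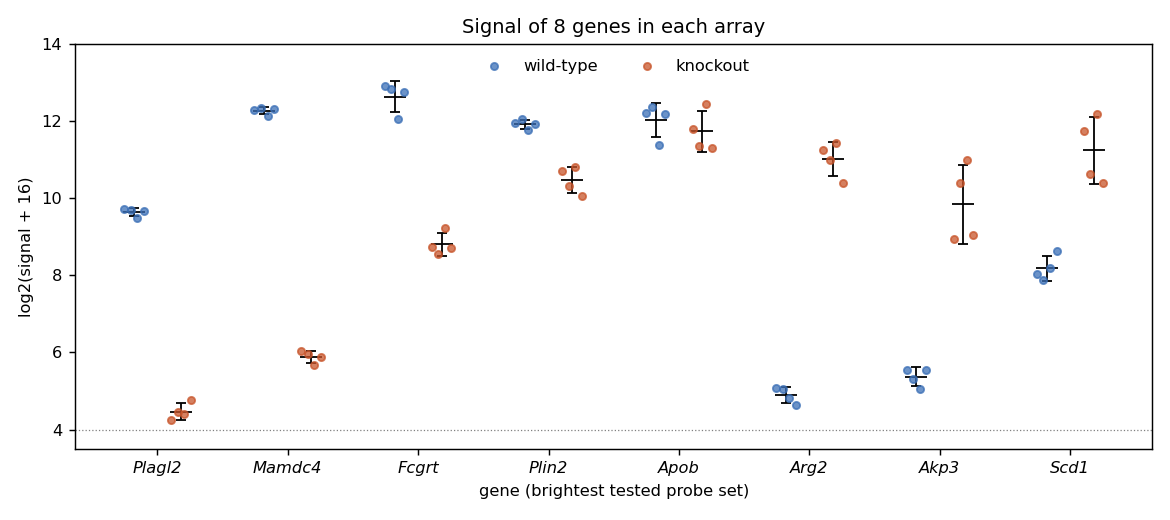
Signal of 8 genes in each array as log2(signal + 16), with 4 wild-type (blue) and 4 knockout (orange) arrays per gene. Black marks are the mean and SD of 4 arrays, and the dotted line is a signal of 0. Mamdc4, Fcgrt and Plin2 lay lower in all 4 knockouts, Arg2, Akp3 and Scd1 lay higher, and the groups overlapped for Apob.

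In all, 3238 of 27022 probe sets (11.98%) passed the threshold, 1427 higher and 1811 lower in the knockout. They represent 966 genes higher and 1227 genes lower, and at least 2-fold differences were called in 379 probe sets higher and 574 lower. The genes Fkbp1a, Rbm39, Serinc3 and Smad4, named after their values were seen, had probe sets called both ways. The number called as higher was 918 without wild-type replicate 1, 880 without knockout replicate 2 and 820 in the 6 arrays without Xist signal. With the 3' to 5' ratio as a covariate, 466 were higher and 916 lower.

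Most chylomicron genes were not called. Of 23 tested genes of chylomicron assembly and triglyceride resynthesis, 2 were higher and 3 lower (2 and 3 adjusted over the list alone), and the list did not pass the set test (mean log2 fold change -0.14, median -0.03, adjusted p = 0.347). The lipid droplet coat genes Plin2 and Plin3 were called as lower. Plin2 (1448318_at) went from 3879 ± 308 to 1438 ± 338 (SD, n = 4, log2 fold change -1.45 ± 0.15, adjusted p = 5.06e-05), and Plin3 fell by 0.70 on the log2 scale. The call of Plin3 ended in an unmoderated linear model (adjusted p = 0.0752). The acyl-CoA synthetase Acsl3 also fell (-0.81), while Dgat1, which makes triglyceride, was called as higher (0.64). The call of Dgat1 ended with the Xist signal (adjusted p = 0.0961) or the 3' to 5' ratio (0.243) as a covariate and in the arrays without Xist signal (0.0746), where 0 genes of the list were higher. Gpat3 was called as higher (0.66), but not without wild-type replicate 2 or knockout replicate 1 or 2 (adjusted p = 0.0595 to 0.067). Apob, the structural protein of chylomicrons, had a signal of 4302 ± 1140 in wild-type and 3576 ± 1430 in knockout samples (SD, n = 4, log2 fold change -0.30, adjusted p = 0.515). The log2 fold changes of Mttp (0.02), Apoa1 (-0.01), Apoa4 (-0.03) and Mogat2 (-0.21), named after their values were seen, also did not pass. Apoa1 signals, 13570 in wild-type and 13440 in knockout samples, lay near the highest signal of each array (13093 to 15256). So did those of Fabp1 in the same list (14000 and 13790). Changes of genes this bright may not show in full, so their flat values are weak evidence of no change. The list as a whole was lower without wild-type replicate 3 (adjusted p = 0.0466), without knockout replicate 3 (0.0102), in the arrays without Xist signal (0.00789), and with the Xist signal (0.0248) or the 3' to 5' ratio (0.0195) as a covariate.

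Genes of cholesterol synthesis were lower as a set. Of 20 tested, 0 were higher and 9 lower (0 and 11 adjusted over the list alone), among them Fdps (-1.11 ± 0.23 SE), Cyp51 (-1.09 ± 0.22), Lss (-1.03 ± 0.17), Tm7sf2 (-0.80 ± 0.13) and Mvd (-0.77 ± 0.15). The list passed the set test (mean log2 fold change -0.49, adjusted p = 2.42e-05), with adjusted p = 0.645 with an estimated correlation. With the 3' to 5' ratio as a covariate the mean was -0.17, 0 genes were lower and the list was not called (adjusted p = 0.163). With Xist as a covariate, or in the arrays without Xist signal, 3 genes were lower, Fdps and Cyp51 not among them (adjusted p = 0.0587 to 0.0788). In sterol uptake and efflux, 4 of 10 were higher and 1 lower (4 and 2 adjusted over the list alone), and the list did not pass (mean 0.43, adjusted p = 0.417). The sterol exporter genes Abcg5 (1.90 ± 0.43 SE) and Abca1 (0.98 ± 0.19) were called as higher, as was Nr1h3 (0.79 ± 0.17), which encodes the sterol-sensing receptor LXR alpha. With the Xist signal or the 3' to 5' ratio as a covariate, and in the arrays without Xist signal, 0 genes of the list were called. Log2 fold changes with the 3' to 5' covariate were 0.84 for Abcg5 (adjusted p = 0.426), 0.62 for Abca1 (0.238) and 0.46 for Nr1h3 (0.322). Abcg8 (1.47) was called as higher and Abcg1 (-0.49) as lower with all 8 arrays. The call of Abcg8 ended without wild-type replicate 1 or 3 or knockout replicate 1, 2 or 3 (adjusted p = 0.0686 to 0.119). That of Abcg1 ended without wild-type replicate 1, 2 or 4 or knockout replicate 1, 2 or 4 (0.0772 to 0.135). In wild-type replicate 3 the mean log2 signal of this list was 7.95, against 8.48 to 8.50 in the other wild-types.

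Fatty acid genes went both ways. For fatty acid oxidation and PPAR targets, 4 of 21 were higher and 1 lower (6 and 5 adjusted over the list alone), with no call for the list (mean 0.23, median -0.0045, adjusted p = 0.55). The receptor gene Ppara (1.27 ± 0.20 SE) and its known targets Vnn1 (2.33 ± 0.42), Pdk4 (1.07 ± 0.20) and Angptl4 (1.06 ± 0.21) were called as higher. With the 3' to 5' ratio as a covariate 0 of the 21 were higher (adjusted p = 0.0991 for Ppara, 0.177 for Vnn1, 0.223 for Pdk4 and 0.0867 for Angptl4), and in the arrays without Xist signal Angptl4 was not called (0.0522). Acaa2 (-0.54) was called as lower, but not without wild-type replicate 1, 2 or 4 (adjusted p = 0.0591 to 0.0726). Among 16 fatty acid synthesis genes, 3 were higher and 5 lower (4 and 6 adjusted over the list alone). The desaturase Scd1 rose from 281 to 2744 (3.06 ± 0.34 SE) and the regulator Srebf1 rose (1.06 ± 0.18). Fads1 (-1.41 ± 0.14) and Fads2 (-0.87 ± 0.15), which desaturate polyunsaturated fatty acids, and the elongase Elovl1 (-0.73 ± 0.09) fell. With the 3' to 5' ratio as a covariate, Srebf1 (adjusted p = 0.136) and Fads2 (0.0641) were not called. This list did not pass the set test (mean 0.02, median -0.14, tested direction lower, adjusted p = 0.363), and with fry its adjusted p was 0.0378.

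Fetal enterocyte genes of uptake and lysosomal digestion fell, with the smallest set test p of the 33 lists. Of 13 tested, 12 were lower and 0 higher (12 and 0 adjusted over the list alone), with a mean log2 fold change of -1.66 (adjusted p = 1.05e-14). Adjusted p was 0.47 with an estimated correlation, and 0.00196 with fry. Fcgrt, which carries maternal IgG across the fetal and neonatal gut, fell from 6513 ± 1560 to 438.5 ± 102 (SD, n = 4). The lysosomal enzyme genes Gusb (-2.37 ± 0.14 SE), Neu1 (-1.89 ± 0.14), Glb1 (-1.88 ± 0.13) and Ctsl (-1.52 ± 0.12) fell with it. Lrp2 (-2.53) and Prdm1 (-0.93), a transcriptional repressor of fetal enterocytes, named after their values were seen, also fell, while Cubn had -0.06 and did not pass. Lrp2 was dim in knockouts (signals 5 to 14), so the size of its change depends on the added 16 (-3.86 to -1.38 over the alternatives). In wild-type replicate 3 the mean log2 signal of this list was 10.26, against 10.86 to 10.97 in the other wild-types.

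Brush border genes split. Of 23 hydrolase and transporter genes, 7 were higher and 5 lower (8 and 7 adjusted over the list alone), and the list did not pass (mean 0.23, adjusted p = 0.518). Akp3 rose from 25.8 ± 6.7 to 1084 ± 745 (SD, n = 4). The fructose transporter Slc2a5 (2.37 ± 0.19 SE), the brush border myosin Myo1a (1.73 ± 0.20) and the aminopeptidase Anpep (1.19 ± 0.15) also rose. The protease gene Mep1a fell (-1.67 ± 0.13). For ileal bile acid handling, 2 of 5 were lower and 0 higher (4 and 1 adjusted over the list alone). They were Nr0b2 (-3.09 ± 0.26 SE) and Nr1h4 (-1.09 ± 0.10), which encode the nuclear receptors SHP and FXR. The size of the Nr0b2 change depended on the processing (-4.11 to -1.95 over the alternatives). That list passed the set test (mean -0.51, adjusted p = 0.00931, and 0.645 with an estimated correlation). Among 9 genes of the urea cycle and arginine metabolism, Arg2 was the 1 higher gene and 5 were lower (1 and 5 adjusted over the list alone). Among the lower genes were Asl (-1.64 ± 0.13 SE), Prodh (-1.62 ± 0.16), Ass1 (-1.06 ± 0.24) and Aldh18a1 (-0.66 ± 0.08). The call of Ass1 ended with the Xist signal (adjusted p = 0.0706) or the 3' to 5' ratio (0.169) as a covariate, and in the arrays without Xist signal (0.0745). Here the set test was lower (adjusted p = 0.00931, and 0.645 with an estimated correlation), as was the median (-0.31), while Arg2 took the mean to 0.05.

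Of 18 enteroendocrine genes 5 were lower and 0 higher (8 and 0 adjusted over the list alone, mean -0.48, adjusted p = 0.00346, and 0.645 with an estimated correlation). The hormone and granule genes Sct (-1.11 ± 0.12 SE), Chgb (-1.04 ± 0.18) and Pyy (-0.80 ± 0.17) were called as lower, Pyy not in an unmoderated linear model (adjusted p = 0.0555). Nts (-1.67) lost its call without wild-type replicate 2 (adjusted p = 0.0503), and Chga (-0.99) without wild-type replicate 1 or 2 or knockout replicate 2 (0.0512 to 0.0555). Among 14 goblet cell genes 4 were higher and 1 lower (7 and 1 adjusted over the list alone, mean 0.23, adjusted p = 0.0671). Spink4 (1.62 ± 0.14) and Agr2 (0.68 ± 0.12) rose, and Guca2a, the precursor of guanylin, fell (-1.98 ± 0.15), the call of Agr2 ending with the 3' to 5' ratio as a covariate (adjusted p = 0.0727). Galnt12 (0.44) and the secreted mucin Muc2 (0.88) were called as higher with all 8 arrays, and lost the call without any 1 of 5 arrays. These were wild-type replicates 1 and 2 and knockout replicates 1, 2 and 4 for Galnt12 (adjusted p = 0.0547 to 0.092). For Muc2 they were wild-type replicates 1 and 3 and knockout replicates 1, 2 and 3 (0.069 to 0.117). The goblet list passed without wild-type replicate 2 or 4 or knockout replicate 2 (adjusted p = 0.0133 to 0.0335).

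For stem and crypt progenitor genes, 5 of 16 were higher and 0 lower (5 and 1 adjusted over the list alone, mean 0.22, adjusted p = 0.0613). It passed without wild-type replicate 1, knockout replicate 2 or knockout replicate 3 (0.0208 to 0.0494). The Wnt target genes Myc (0.76 ± 0.14 SE) and Axin2 (0.79 ± 0.16) were called as higher, but not with the 3' to 5' ratio as a covariate (adjusted p = 0.132 and 0.258), where 0 of the 16 were called. Cd44 (0.49), Smoc2 (0.70) and Prom1 (0.68) were called as higher. Their calls ended without wild-type replicate 2 or 4 or knockout replicate 1 or 2, for Cd44 and Prom1 also without wild-type replicate 1, and for Prom1 without knockout replicate 4. Adjusted p was then 0.0513 to 0.0652 for Cd44, 0.0521 to 0.0666 for Smoc2 and 0.0641 to 0.0833 for Prom1. Cell cycle genes were slightly higher as a set (27 tested, mean 0.27, adjusted p = 0.00209, and 0.757 with an estimated correlation), 3 of them higher and 0 lower (0 and 0 adjusted over the list alone). These were Aurkb (0.62), Cdc20 (0.49) and Pcna (0.38). Their calls ended without any 1 array (adjusted p = 0.0819 to 0.114, 0.0789 to 0.0996 and 0.0592 to 0.131), except wild-type replicate 3 and, for Aurkb and Cdc20, knockout replicate 3. Of 9 Paneth and antimicrobial genes, lysozyme Lyz1 (0.82) was the 1 called (1 and 0 adjusted over the list alone, list mean 0.18, adjusted p = 0.417). Lyz1 lost the call without wild-type replicate 2 or knockout replicate 1 (0.0528 to 0.0555).

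Outside the epithelium, smooth muscle genes were higher as a set (13 tested, 2 higher, 0 lower, 2 and 0 adjusted over the list alone, mean 0.43, adjusted p = 0.00346, and 0.645 with an estimated correlation). Synm had 0.96 ± 0.15 (SE) and Smtn 0.67. The list of mesenchyme and extracellular matrix was higher too (18 tested, 2 higher, 0 lower, 2 and 0 adjusted over the list alone, mean 0.36, adjusted p = 0.00105, and 0.649 with an estimated correlation). Fbln1 had 0.66 ± 0.10 (SE) and Col6a1 0.46, and Fbln1 was not called with the 3' to 5' ratio as a covariate (adjusted p = 0.0669) or by the mean of its probe sets (0.163). Single left-out arrays ended the calls of Smtn (wild-type replicates 1 and 2, knockout replicates 1 and 2, adjusted p = 0.0522 to 0.0603) and Col6a1 (those 4 and wild-type replicate 4, 0.0508 to 0.0699). Macrophage and leukocyte genes were lower (17 tested, 2 lower, 0 higher, 3 and 0 adjusted over the list alone, mean -0.38, adjusted p = 0.00723, and 0.645 with an estimated correlation). The receptor gene Csf1r fell from 3752 to 707 (-2.38 ± 0.14 SE) and Adgre1 fell by 0.98 on the log2 scale. That set was not called in the 6 arrays without Xist signal (adjusted p = 0.0919) or with Xist as a covariate (0.0848), and Adgre1 was not called with the 3' to 5' ratio as a covariate (0.0926).

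Lymphatic endothelium, whose vessels take up chylomicrons, had 1 of 12 genes higher and 0 lower (0 and 0 adjusted over the list alone, mean 0.03, adjusted p = 0.77). This gene, Pdpn (0.52), lost its call without any 1 array other than knockout replicate 3 (0.0699 to 0.132). In blood endothelium 0 of 16 were called by limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, mean -0.01, median 0.04, adjusted p = 0.87). Plvap had -0.30, Tek -0.25 and Esam -0.20, and Plvap was called without wild-type replicate 3 (0.0438). Of 17 genes of enteric neurons and glia, S100b (-0.89) alone was called (0 adjusted over the list alone, list mean 0.26, adjusted p = 0.0613). It was not called without wild-type replicate 1, 2 or 4 or knockout replicate 1, 2 or 3 (0.058 to 0.116). That list was higher without wild-type replicate 1 or 3 or knockout replicate 3 (0.00578 to 0.0456). Among 7 mesothelium genes, Upk3b fell (-1.17 ± 0.13 SE) and Krt19 rose (0.70 ± 0.11), with the same counts adjusted over the list alone (mean 0.11, adjusted p = 0.55). Krt19 was not called with the 3' to 5' ratio as a covariate (0.0554).

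Neighbouring tissues were also looked for. Of 9 liver genes, Ttr (-1.87 ± 0.37 SE) and Afp were lower and 0 higher, with the same 2 adjusted over the list alone (mean -0.44, adjusted p = 0.417). Ttr was not called with the Xist signal (adjusted p = 0.0677) or the 3' to 5' ratio (0.136) as a covariate. Without knockout replicate 4 the liver list was lower (mean -1.34, adjusted p = 0.00477). Albumin (Alb) gave 4646 in knockout replicate 4, 656 in knockout replicate 1 and 4 to 122 in the other 6 arrays. Pancreas genes had 0 of 14 called by limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, mean 0.16, adjusted p = 0.77). Cela1 had -0.49, Ins2 0.73 and Cpb1 0.79. Of 6 stomach genes Tff2 (-2.56) was called (1 adjusted over the list alone, mean -0.65, adjusted p = 0.417). It lost the call without wild-type replicate 1, 2 or 4 or knockout replicate 1 or 3 (0.0808 to 0.106). The colon and erythroid lists had 3 tested genes each and no set test. The carbonic anhydrase gene Car4 was higher (2.59 ± 0.35 SE, 17.3 to 175). The erythroid genes Alas2 (0.64), Slc4a1 (1.30) and Klf1 (0.17) were not called, although Slc4a1 was without knockout replicate 3 (0.0286). Counts adjusted over the list alone were the same for these 2 lists.

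Among response pathways, hypoxia and glycolysis genes were higher as a set (18 tested, 5 higher, 0 lower, 12 and 0 adjusted over the list alone, mean 0.42, adjusted p = 0.00105, and 0.645 with an estimated correlation). The carbonic anhydrase gene Car9 rose from 125 to 622 (2.17 ± 0.16 SE), and P4ha1 (0.86 ± 0.15) and Pgam1 (0.34 ± 0.08) rose. Pdk1 (0.97) was called but not without wild-type replicate 2 or knockout replicate 2 (0.0724 to 0.0742). Egln3 (0.58) was not called without wild-type replicate 1, 2 or 3 or knockout replicate 2 or 3 (0.0618 to 0.12). With the Xist signal as a covariate neither the set (adjusted p = 0.0682) nor Pgam1 (0.1) was called, and in the arrays without Xist signal Pgam1 was not (0.0879). Genes of oxidative phosphorylation were lower (19 tested, 4 lower, 0 higher, 6 and 0 adjusted over the list alone, mean -0.18, adjusted p = 0.00105, and 0.645 with an estimated correlation). Ndufs1 (-0.37 ± 0.08 SE) and Ndufs3 (-0.34 ± 0.07) were called as lower. With the 3' to 5' ratio as a covariate 0 of the 19 were (adjusted p = 0.17 for Ndufs1 and 0.128 for Ndufs3), while the list was still called (0.00766). Calls of Sdha (-0.35) ended without wild-type replicate 1 or 2 or knockout replicate 1 (0.0531 to 0.0678). Those of Sdhb (-0.33) ended without these and without wild-type replicate 4 or knockout replicate 2 or 4 (0.0591 to 0.0872).

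Genes of endoplasmic reticulum stress were lower (18 tested, 6 lower, 0 higher, 8 and 2 adjusted over the list alone, mean -0.21, adjusted p = 0.0332, and 0.645 with an estimated correlation). Dnajb9 (-1.08 ± 0.18 SE), Sel1l (-0.72 ± 0.11), Pdia4 (-0.66 ± 0.12), Creld2 (-0.61 ± 0.13) and Hsp90b1 (-0.35 ± 0.08) were called as lower. With the 3' to 5' ratio as a covariate 2 genes were lower, Pdia4 (adjusted p = 0.0765), Creld2 (0.18) and Hsp90b1 (0.285) not among them, and the list was not called (0.147). The list was not called without wild-type replicate 2, knockout replicate 1 or knockout replicate 4 (adjusted p = 0.0695 to 0.085). Of 15 glucocorticoid and fasting genes 5 were higher and 3 lower, with the same counts adjusted over the list alone (mean 0.25, adjusted p = 0.609). Fkbp5 (1.24 ± 0.18 SE) and Cdkn1a (1.31 ± 0.23) were called as higher, Cdkn1a not with the 3' to 5' ratio as a covariate (adjusted p = 0.0888). Hif3a (-1.59 ± 0.10) and Tsc22d3 (-1.10 ± 0.21) were called as lower, Tsc22d3 not in an unmoderated linear model (0.0692). Metallothionein Mt1 (1.11) was called but not without wild-type replicate 1, 2 or 4 or knockout replicate 2 (0.063 to 0.0791). In the interferon response Ifit1 (-1.91 ± 0.43) was the 1 gene called of 12 (1 adjusted over the list alone, mean -0.25, adjusted p = 0.529). Ifit1 was not called with the Xist signal (0.114) or the 3' to 5' ratio (0.207) as a covariate, or in the arrays without Xist signal (0.115). Without knockout replicate 4 that list was lower (mean -0.76, adjusted p = 0.00612).

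**Figure D2:**
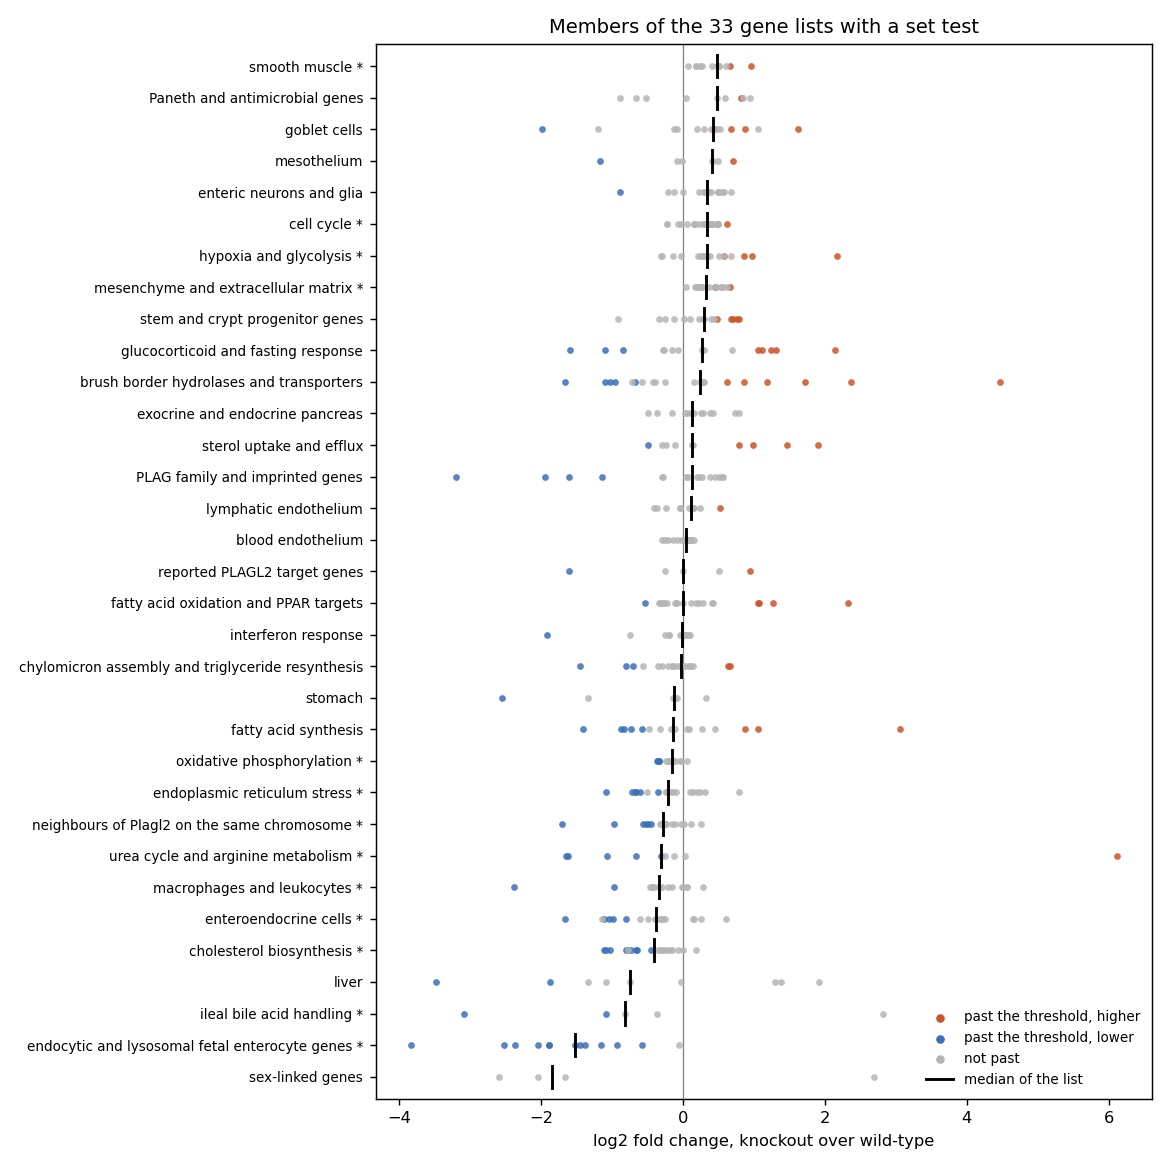
Log2 fold change, knockout over wild-type, of each tested member of the 33 gene lists with a set test, as points. Orange and blue points passed the threshold as higher and lower, grey points did not, black bars are list medians, and a star marks the 13 lists past the set test with a preset correlation. The fetal endocytic and lysosomal list has 12 of 13 members called lower.

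The imprinted genes Igf2, Cdkn1c and Igf2r fell, in a list that did not pass. Of 16 PLAG family and imprinted genes 4 were lower and 0 higher (4 and 1 adjusted over the list alone, mean -0.33, median 0.13, tested direction lower, adjusted p = 0.366). The growth factor gene Igf2 fell from 5825 to 1912 (-1.60 ± 0.08 SE), the growth inhibitor Cdkn1c from 5968 to 653 (-3.20 ± 0.17) and Igf2r from 1377 to 616 (-1.14 ± 0.09), all with all 4 knockouts below all wild-types. Gatm (-1.94) lost its call without wild-type replicate 1, 2 or 4 (0.052 to 0.0577). Among 5 tested genes reported as PLAGL2 targets, Igf2 was lower and the Wnt receptor gene Fzd2 (0.95) was called as higher (1 and 2 adjusted over the list alone, mean -0.08, median 0.0019, adjusted p = 0.71, and 0.00517 with fry). Fzd2 lost its call without wild-type replicate 1 or 4 or knockout replicate 1, 2 or 4 (0.0667 to 0.083).

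Genes beside Plagl2 on its chromosome were lower. Of 18 tested neighbours 6 were lower and 0 higher (6 and 0 adjusted over the list alone, mean -0.35, adjusted p = 0.00151, and 0.47 with an estimated correlation). Nol4l (-1.71 ± 0.10 SE, 982 to 288) and Pofut1 (-0.96 ± 0.13, 786 to 394), an O-fucosyltransferase of Notch receptors, fell by all of their tested probe sets, 2 of 2 and 3 of 3. Mapre1 (-0.56 ± 0.12) was called as lower by 1 of 5 probe sets, but not by the mean of them (adjusted p = 0.272), with the Xist signal (0.0983) or the 3' to 5' ratio (0.158) as a covariate, or in the arrays without Xist signal (0.0882). Commd7 (-0.52), Tm9sf4 (-0.45) and Dnmt3b (-0.49) were called by 1 of 2 each, and their calls ended without single arrays. For Commd7 these were wild-type replicates 1 and 4 and knockout replicate 1 (0.0561 to 0.0697), and for Tm9sf4 wild-type replicate 2 and knockout replicates 1 and 2 (0.0522 to 0.0644). For Dnmt3b they were all arrays but knockout replicate 4 (0.0819 to 0.123). Of 4 tested sex-linked genes 0 were called (1 higher and 3 lower adjusted over the list alone, mean -0.90, adjusted p = 0.369). Xist had 2.69, Uty -2.04 and Eif2s3y -2.59. Knockout replicates 2 and 3 alone had the Xist signal of females, so the lack of calls does not mean that sex was balanced. Calls came without knockout replicate 1 for Xist (0.0327), without knockout replicate 1 or 4 for Uty (0.0162 to 0.035) and without knockout replicate 4 for Eif2s3y (0.0328).

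**Figure D3:**
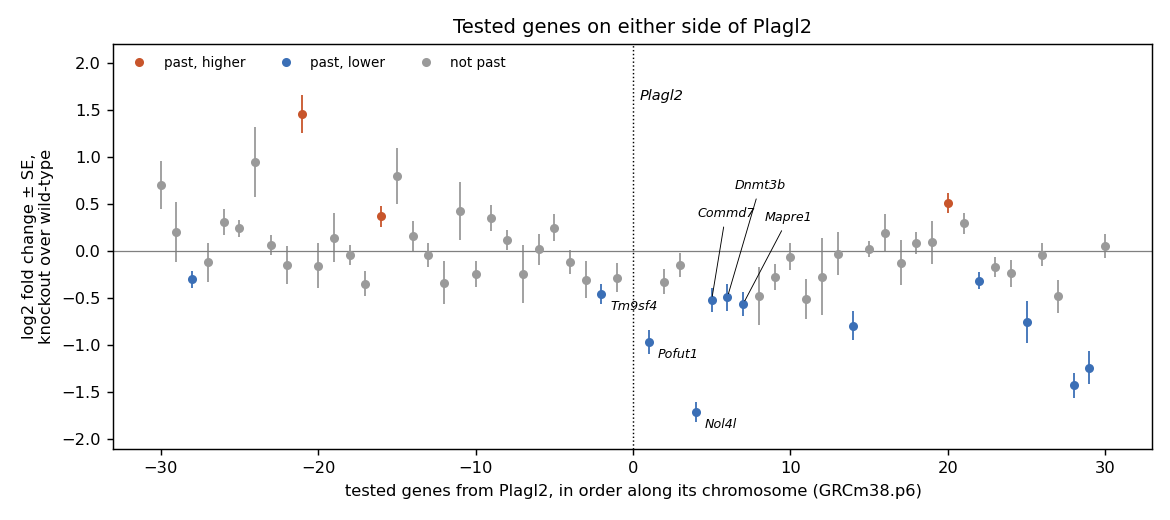
Log2 fold change with standard error of the 30 tested genes on each side of Plagl2, in their order along the chromosome in GRCm38.p6, with Plagl2 itself at the dotted line and not drawn. Blue and orange points passed the threshold as lower and higher, grey points did not. The 6 lower genes of the list lie within 10 tested genes of Plagl2, and Nol4l has the lowest value.

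With an estimated correlation 0 of the 33 lists passed the camera test and 8 passed with fry. Some lists called with the preset correlation failed with fry too. Among these, oxidative phosphorylation and the urea cycle list had a fry adjusted p of 0.0569. Cholesterol synthesis and endoplasmic reticulum stress had 0.0706. Smooth muscle had 0.134, mesenchyme and extracellular matrix 0.161 and the cell cycle 0.234. Before adjustment, camera gave p under 0.05 for 2 lists with an estimated correlation, the neighbours of Plagl2 (0.0207) and the fetal endocytic and lysosomal genes (0.0285).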

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

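Of the tests of explanations below, the count of splits was planned before the data were examined, and all others, with their limits, were chosen after the results were seen. The 8 arrays were split into 4 and 4 in all 35 ways, to see how many probe sets chance would call. The real split, itself 1 of the 35, called the most (3238), and the highest of the others gave 711. This argues against chance as the source of that number, but so few splits cannot exclude it. Nor can the splits tell genotype from other differences that follow it.

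The 13 tested endocytic and lysosomal genes of fetal enterocytes had a mean log2 fold change of -1.66. A lower share of epithelium in the knockout samples as the whole cause is argued against by 17 epithelial identity genes, with a mean of 0.17. Its SE of 0.17 is taken across the genes and does not measure the spread between arrays. The genes were mixed, 4 called as higher and 2 as lower, from -1.02 (Krt18) to 1.85 (Cldn3). Smooth muscle (0.43) and mesenchyme (0.36) were higher as sets with the preset correlation, but not with an estimated one (camera adjusted p = 0.645 and 0.649). A smaller shift between tissues is therefore not excluded. Less distal intestine in the knockout samples cannot be told apart from the genotype, since the median of the distal bile acid genes was -0.37 but the 3 that were tested ran from -0.81 ± 0.25 (SE, Slc51b) to 2.82 ± 1.10 (SE, Fabp6). Neither was called with all 8 arrays. Slc51b was called as lower without wild-type replicate 3 or knockout replicate 3 (adjusted p = 0.0082 to 0.0175). Fabp6 was called as higher without knockout replicate 4 (0.0317). An earlier adult-type programme in the knockout may account for the pattern. Of 7 genes that rise at weaning 5 were tested, with a mean of 0.71. Their camera p was 0.0249, not adjusted over the lists made for these tests, and 0.24 with an estimated correlation. Mgam (0.86) alone was called, the others having adjusted p of 0.115 (Ada) to 0.817 (Treh). The earlier programme is a hypothesis found and tested on the same arrays. With the 3' to 5' ratio as a covariate the mean of the fetal list was -1.95 with 12 of 13 lower. That ratio follows the genotype without overlap, so this fit cannot tell the difference in RNA from the genotype, and no conclusion is drawn from it.

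Albumin stood at 4646 in knockout replicate 4 and at most 656 elsewhere. A wrong genotype label is argued against by the Plagl2 signal of that array, 11 against 697 in the lowest wild-type. Liver RNA in the sample could be the source, since 10 of 12 liver genes other than Afp and Ttr had their highest signal there (Alb, Ahsg, Fgb, Fga, Fgg, Hpx, Serpina1b, Kng1, F2 and Apoh), Fga at 1161 against 558 in the next array. Alb, whose signal raised the question, is 1 of the 10 and adds no support of its own. Fga also gave 209 to 558 in wild-types, where its source was not tested, so a biological difference of knockout replicate 4 stays open and untested.

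Of the 10 tested genes on each side of Plagl2, 30% were called lower, against 5.56% of those 11 to 100 genes away (Fisher's exact p = 0.00197). The lower genes within 10 are the same that raised the question, so this test describes the pattern and cannot support a cause. An effect of the targeted allele on its immediate neighbours may account for them. Variants of another mouse strain carried with the targeted allele could also do so, since 3 of the 4 genes with probe sets called in both directions lie within 100 tested genes of Plagl2 (3 of 92 genes with several probe sets, against 1 of 5884 elsewhere, Fisher's exact p = 1.4e-05). Both stay open, and so does regulation by the missing factor itself, which was not tested. These distances were chosen after 7 windows had been looked at, in which the share called lower was 30% within 10 genes, 18% within 25, 14% within 50, 9.33% within 75, 8% within 100, 7.33% within 150 and 8.5% within 200. The test of genes called both ways was chosen after seeing where they lie. Gss (-1.43) and Myh7b (-1.24), 28 and 29 genes from Plagl2, fell more than any lower gene within 10 other than Nol4l (-1.71). Of the 180 genes 11 to 100 away, 10 were lower and 17 higher. Both Fisher tests treat linked genes on the same arrays as independent.

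In 26 of 436 groups of 4 arrays, 1 array lay far from the other 3 (its gap to the nearest, over the range, was above Dixon's critical value, for signals on the log2(signal + 16) scale), where chance gives about 21.8. Of these, 16 were in wild-type replicate 3. The values below are raw signals unless they are said to be others. Its Stra6l signal was 277, with 721 to 836 in the other wild-types. Fdps gave 2896 there (2281 to 2363 in the others). Nr1h3 gave 62 (107 to 117). Myo1a gave 305 (547 to 594). Nr0b2 gave 138 (267 to 296). Nts gave 235 (496 to 547). Plvap gave 361 (468 to 478). Tff2 gave 103 (372 to 426). Gatm gave 76 (428 to 477). Alpi gave 3759 (5547 to 6009). Atp6v1b2 gave 2138 (2680 to 2764). Slc51a gave 1141 (1558 to 1626). Slc51b gave 267 (482 to 533). Its value on the principal component that separates the genotypes was -21.9 (-44.7 to -43.3). The mean log2 signal of the sterol uptake and efflux list was 7.95 (8.48 to 8.50), and that of the fetal endocytic and lysosomal list 10.26 (10.86 to 10.97).

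Prox1 gave 8 in wild-type replicate 4 (26 to 30 in the others). In knockout replicate 1, Cpb1 gave 642 (53 to 80) and Mt1 gave 6797 (7601 to 7639). In knockout replicate 3, St3gal1 gave 35 (44 to 46), Creld2 gave 379 (256 to 272) and Lrp2 gave 14 (5 to 6). The mean log2 signal of the endoplasmic reticulum stress list was 8.98 there (8.66 to 8.70) and that of the neighbours of Plagl2 was 7.51 (7.62 to 7.63). In knockout replicate 4, Ppara gave 395 (752 to 762) and Pyy gave 59 (105 to 108).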

How the results depend on the processing

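No result changed direction past its threshold under any alternative, and 0 of the called probe sets shared with the reported ones changed sign in any refit. Signs could not change with the filters, the replicate block, no intensity trend, the unmoderated model or stricter thresholds, which keep the fold changes. In the other refits only probe sets called both times were compared, so this is a weak check. The named genes kept their side of the threshold in 3799 comparisons with an alternative, lost it in 446 and gained it in 40, and the lists in 696, 31 and 32. The 2 fits without outlying or Xist-bearing arrays were chosen after seeing the data. The reported 3238 called probe sets (1427 higher and 1811 lower, as 966 and 1227 genes) became 2807 without a filter, 3311 after quantile normalization and 4329 without the 2 most distant arrays.

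The replicate block gave 1915 (751 higher and 1164 lower, 524 and 796 genes). The 4 correlations of arrays with the same number, within groups centred, were -0.274 to -0.0111 and gave no sign of pairing. So few arrays cannot exclude shared litters. Array weights gave 5215, with 2631 higher and 1741 genes higher. The Xist covariate gave 2024, with 755 higher and 551 genes higher, and the 6 arrays without Xist signal gave 2152, with 820 and 604. The 3' to 5' ratio as a covariate gave 1382 (466 higher and 916 lower, 342 and 646 genes), and that ratio follows the genotype without overlap. For these settings the cause was not tested. The unmoderated model gave 883 higher and 637 genes higher. An adjusted p under 0.01 gave 1720 (660 and 1060, 463 and 728 genes), and a 1.5-fold minimum gave 928 higher, by their construction.

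Without 1 array each, called probe sets numbered 2227 to 4251, of which 880 to 2082 were higher and 1302 to 2169 lower, with 609 to 1384 genes higher. The lowest counts of higher probe sets were without knockout replicate 2 (880) and wild-type replicate 1 (918), the highest without wild-type replicate 3. The difference in 3' to 5' ratio was 0.0475 to 0.0744, with exact permutation p of 0.0571 or more without 5 single arrays. With an estimated correlation 0 lists passed. With fry 8 did, 6 of the 13 called lists and 2 others, fatty acid synthesis and reported PLAGL2 targets. The 18015 dimmer probe sets, whose signals lie near the background of the array, were tested in the fit without a filter alone.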

Other observations

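The genes and groups named here were chosen after their values were seen. A screen of 170 families of genes that share the letters at the start of their symbol (at least 10 tested genes each) found 4 families lower and 2 higher with the preset correlation. With an estimated correlation 0 of the 170 passed the camera test, and 4 had an unadjusted p under 0.05. Of 10 Commd genes 6 were lower and 0 higher (adjusted p = 0.00165, and adjusted p = 0.55 with an estimated correlation). Of 28 sorting nexin (Snx) genes 8 were lower and 1 higher (0.00165, and 0.984 with an estimated correlation), and of 34 Vps genes 11 were lower and 1 higher (0.0165, and 0.984). Other families of membrane trafficking did not pass, among them Rab (2 of 65 higher and 12 lower, adjusted p = 0.204), Trappc (0.285), the AP family (0.309) and Chmp (0.779, with 2 of 10 higher and 0 lower). Of 63 Atp genes 16 were lower and 4 higher (0.0108, and 0.984 with an estimated correlation). Among the 18 tested genes of the vacuolar proton pump, which acidifies endosomes and lysosomes, 12 were lower and 1, Atp6v0a2 (0.66), higher, the last not with the 3' to 5' ratio as a covariate (adjusted p = 0.0867). Atp6v1b2 fell from 2578 ± 295 to 860.5 ± 77.4 (SD, n = 4), and Tcirg1 (-1.55), Atp6v1a (-0.81) and Snx8 (-2.06) also fell. Cytochrome P450 genes went the other way, with 13 of 33 higher and 3 lower (adjusted p = 0.0017, and 0.55 with an estimated correlation), among them Cyp4f16 (2.71), Cyp2s1 (2.47) and Cyp27a1 (2.10), as did carboxylesterase (Ces) genes, with 4 of 10 higher and 0 lower (0.042, and 0.984 with an estimated correlation).

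Further single genes changed several-fold with no overlap between the groups. The folate receptor Folr1 fell from 3086 ± 510 to 311.5 ± 63.4 (SD, n = 4, log2 fold change -3.25), the zinc transporters Slc30a2 (-3.15) and Slc39a8 (-2.85), the phosphate transporter Slc34a3 (-3.36) and the oxidase Nox4 (-3.41) fell, and Krt20, a keratin of differentiated enterocytes, rose from 526.5 ± 99 to 3220 ± 932 (2.55). Slc16a5 (3.17) and Slc5a4b (2.77) rose. Slc16a5 was dim in wild-types (signal 10.25 ± 8.06, SD, n = 4), so the size of its change depends on the added 16 (1.91 to 4.61 over the alternatives). Of the tight junction genes, Cldn2 fell (-2.29) and Cldn3 rose (1.85). Among 7 proximal small intestine genes 0 were higher and 1, the iron exporter Slc40a1 (-0.68), was lower, with a mean of 0.0028.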
